A study of Homo sapiens with 16 samples.

How the data were processed

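RNA was sequenced from nuclei of 2 human cell lines, K562, an erythroleukemia line, and H1, an embryonic stem cell line. The nuclei had been separated into RNA held on chromatin and RNA in the soluble part of the nucleus. The labels describe 16 libraries: 3 of chromatin RNA and 3 of soluble nuclear RNA from untreated K562 cells, 3 and 3 from H1 cells, and 2 and 2 from K562 cells given 50 µM hemin. The tables used here hold 1 value per feature and fraction for each line. The K562 table names no treatment and was read as untreated cells, so 12 libraries stand behind the values as far as the table names show. The 4 hemin libraries were not analysed here.

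The FPKM values (fragments scaled to feature length and sequencing depth) were used as deposited. The table headers name no unit, and FPKM was inferred from the form of the numbers and from Cuffdiff, which is named with TopHat2 and the genome build hg38, without versions, per the submitters' processing notes. A stranded library kit is named, per the labels' protocols. How strand was used in counting, the annotation, the assembly of unannotated features and the rule behind the authors' class cheRNA (chromatin-enriched RNA) are not given in the sources used here. The authors' 3 classes, mRNA, lincRNA and cheRNA, were used as given. The libraries of a fraction were pooled to 1 value, so no spread between replicates, standard error or test of a single gene could be had. Total counts per library are unknown, and no interval that needs them is given. The design fixed before the data were examined foresaw a test per transcript, which these values do not allow. Membership of the class cheRNA is therefore the only call of enrichment, and other features are described by their 2 values.

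Differences are on the scale log2(FPKM + 0.1), chromatin minus soluble nuclear RNA, which understates the difference of weakly expressed genes. Features averaging under 0.1 FPKM over the 2 fractions were left out of the class and list summaries. Entries of a class with the same location and the same pair of values were counted as 1 feature, since they share 1 estimate. There were 869 such sets in K562, with 2273 symbols, and 949 in H1, with 2466 symbols. A location over 5 Mb long was called a merged locus. Of the cheRNAs, 29 in K562 and 6 in H1 have the location and values of an annotated entry, and these were left out of the analyses of position. No fold is given against a fraction listed at 0. No other column of numbers in the tables was left unused.

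Positions are on hg38 as the tables give them. Coding genes were placed with a RefSeq table of assembly GRCh38.p14, the same build. It matched 18905 of 19734 mRNA symbols in K562 and 18607 of 19428 in H1, and 15629 and 17309 coding genes outside merged loci were used. Annotated lincRNAs at or above the filter were placed at their own location, or at RefSeq's where the location was shared. Gaps between features ignore strand.

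Shares of features are given with exact Clopper-Pearson 95% intervals, which cover counting error over features only. Features are not replicates, so Fisher tests between classes, although foreseen, are left out and odds ratios are given. The 12 gene lists were fixed before the data were examined. Each list median was placed among 10000 random lists of the same size, matched on mean abundance in 10 bins. This describes the pooled libraries at hand and is not a test of the cell lines. The random lists were drawn from mRNAs and lincRNAs together and were not matched on class or gene length. Coding genes whose nearest noncoding transcript within 100 kb was a cheRNA were compared with those whose nearest was an annotated lincRNA, in a two-sided permutation test of the difference of medians with 100000 random relabelings of genes. The K562 to H1 comparison of coding genes near cheRNAs used the same test. The tables of the 2 lines were normalized separately, so levels across them were set relative to the median over shared genes. Intervals on these differences come from 2000 resamplings of genes and do not cover the spread between cultures.

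The named features followed a rule fixed before the data were examined: the 6 largest and 6 smallest differences per line among annotated features averaging at least 1 FPKM, the 6 cheRNAs highest in chromatin, 2 to 4 members per list, those with the largest differences, 11 fixed genes wherever measured, and noncoding transcripts from HBB to HBE1 with 25 kb either side. Members with both fractions above 0 are given in place of those listed at 0, which are named as such. List members outside that rule, such as those nearest to balance or on the other side from most of their list, were picked after their values were seen. Other features picked that way are said to have been chosen after their values were seen. Some list members that the rule would name are not reported here. Alternatives included other pseudocounts, filters, fold requirements, windows and scalings.

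The procedures were tested on simulated data. In the K562 test of 15629 genes, 7 of 100 simulations without an effect passed a share of 0.05, and a simulated shift of 1 was recovered as 0.997 on average and passed in 20 of 20. These simulations shuffled the values over genes, which removes any likeness between neighbouring genes. They therefore cannot show how the test behaves where neighbours are alike. For lists of 25 among 12127 K562 features, 6 of 100 unchanged lists fell outside the central 95% and 93 of 100 lists shifted by 1 lay above the 97.5 percentile. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.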

Results

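Nuclear RNA was measured in 2 fractions of K562 and H1 cells, RNA held on chromatin and RNA in the soluble part of the nucleus. The series title names chromatin-enriched noncoding RNAs, their cell type specificity and the genes near them. The K562 table has 31014 entries, of which 19817 are mRNAs, 7904 lincRNAs and 3293 cheRNAs, the authors' class of chromatin-enriched RNAs. The H1 table has 28483 entries, with 19510 mRNAs, 7837 lincRNAs and 1136 cheRNAs. Each value pools the 3 libraries of a fraction, so no value has a replicate error, and the depth is unknown.

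In K562 cells, mRNAs of erythroid, housekeeping and ribosomal protein genes mostly had higher FPKM in soluble nuclear RNA, while MEG8, PVT1 and FTX, noncoding RNAs, were higher on chromatin. FPKM is relative to all RNA of a fraction, so these differences do not show where most copies of an RNA lay. The fetal and embryonic globin genes HBG1, HBG2 and HBE1 shared 1 feature with the olfactory receptor gene OR51B5. It had 524 FPKM in chromatin and 11120 FPKM in soluble RNA, a log2 difference of -4.41. PVT1, a noncoding RNA next to MYC, had 666 FPKM in chromatin and 246 FPKM in soluble RNA. The cytokine gene IL32 had the largest difference among annotated features averaging at least 1 FPKM and above 0 in both fractions, at 5.45 on the log2 scale, with 8.73 FPKM in chromatin and 0.102 FPKM in soluble RNA. With a pseudocount of 1 it fell to 3.14, below RANBP1, whose high values such a pseudocount hardly moves. The splicing factor gene SMU1 had the lowest difference, at -10.83, with 0.0872 FPKM in chromatin and 340 FPKM in soluble RNA. With a pseudocount of 0.01 PAGE1 lay lower, at -11.84 against -11.77 for SMU1.

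After IL32, the annotated K562 features highest on chromatin were MEG8, an imprinted noncoding RNA, at 5.31, EIF2S3L at 4.64 and RANBP1, a regulator of the GTPase Ran, at 4.56. The taste receptor gene TAS2R19 followed at 4.45 and the olfactory receptor gene OR51I1 at 4.20. OR51I1 has the location of the globin feature above, chromosome 11 from 5248082 to 5645789, with other values. Its estimate therefore does not come from a location of its own. RPS29, RP11-109M17.2, ANKRD28, RP11-330A16.1 and MIR3180-4 were listed at 0 in soluble RNA, with 63.0, 51.9, 27.8, 6.69 and 4.98 FPKM in chromatin. RPS29 encodes a ribosomal protein that every cell uses, so a value of 0 can be a failed estimate. At the other end, the cancer-testis antigen genes PAGE1 and MAGEC2 stood at -8.53 and -8.23. NDUFB7, a subunit of respiratory complex I, stood at -8.17, the mannosidase gene MAN1A1 at -8.11 and NUDT4 at -7.72. PAGE1, MAGEC2, NDUFB7 and MAN1A1 had only 4.08e-05, 0.00084, 0.0089 and 0.0036 FPKM in chromatin. Values this near 0 can be failed estimates too. An annotated feature on chromosome 17, from 19111999 to 19112636, was listed at 0 in chromatin with 27.2 FPKM in soluble RNA.

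All 25 measured erythroid features of K562 were lower in chromatin, 23 of them by at least 3-fold. Their median of -3.17 lay at percentile 0.43 of random lists, whose median was -2.24, and with a pseudocount of 1 at percentile 3.84, inside the central 95%. The hemoglobin chaperone AHSP had 0.634 FPKM in chromatin and 29.4 FPKM in soluble RNA. The erythroid transcription factor GATA1 had 4.13 and 56.3 FPKM, a difference of -3.74. SLC25A37, a mitochondrial iron importer, was the member nearest to balance, at -0.36. All 24 measured housekeeping features were lower in chromatin by at least 3-fold, with a median of -3.95 at percentile 0.27. Among them B2M stood at -6.03, EEF1A1 at -4.71, GAPDH at -4.39 and ACTB at -3.87.

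Of 77 ribosomal protein features in K562, 70 were lower in chromatin, and their median of -4.21 lay below all 10000 random lists. RPL23A stood at -7.11 and RPS3A at -5.67, whereas RPL10 was higher in chromatin, at 2.61. RPL10 had 219687 FPKM in chromatin and 35969 FPKM in soluble RNA. It is among the 33 K562 features above 2000 FPKM in chromatin, of which 97.0% held a small structured RNA. Reads of a small RNA may therefore set its value, a doubt that also holds for RANBP1, SNHG15 and other features this high. The 3 features of mitochondrially encoded RNAs had a median of -6.09, also below all random lists, and the largest had 103 FPKM in chromatin and 7016 FPKM in soluble RNA. Of 48 replication-dependent histone features 44 were lower in chromatin, with a median of -3.34 at percentile 0.2, and at 3.86, inside the central 95%, among features averaging at least 1 FPKM. HIST1H2AC stood at -6.44 and HIST1H4J at -4.75. The 16 heme and oxidative stress features were all lower in chromatin, with a median of -2.71 at percentile 11.8. Ferritin light chain (FTL) stood at -4.30 and NQO1 at -4.15.

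The nuclear lncRNAs of K562 had a median of 0.48, above all 10000 random lists of like abundance, whose median was -2.11. Those lists were not matched on class, and all K562 lincRNAs had a median of -0.81 against -1.92 for mRNAs. Class may therefore account for part of that distance. Of the 6 measured nuclear lncRNAs, MEG8, PVT1 at 1.44 and FTX at 1.21 were higher in chromatin. JPX stood at -0.76, MIAT at -0.57 and MEG3 at -0.25. MALAT1 and NEAT1 were listed at 0 in both K562 fractions, inside a merged locus of chromosome 11. The snoRNA host and cytoplasmic lncRNAs had a median of -2.31 at percentile 75.1, with 9 of 12 lower in chromatin. SNHG6 stood at -3.99 and SNHG5 at -3.67, while SNHG15 was higher in chromatin at 2.25. RMRP, the RNA of a nuclear endoribonuclease, had 178549 FPKM in chromatin and 238127 FPKM in soluble RNA, and the telomerase RNA TERC had 1005 and 844 FPKM.

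Genes of other fates were also measured in K562. The 7 myeloid and megakaryocyte features had a median of -2.79 at percentile 3.33, against a random median of -1.67, with LYZ at -5.21 and CD33 at -4.07. The 6 germ layer features had a median of -2.16 at percentile 14.1, with KRT18 at -2.81 and COL1A2 at -2.61. The 7 pluripotency features had a median of -2.09 at percentile 8.68, with LIN28B at -3.87. POU5F1 and SOX2 were listed at 0 in K562 chromatin, and NANOG was listed at 0 in soluble RNA.

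Over all annotated K562 features, 1219 were higher and 10908 lower in chromatin, with a median of -1.79. Centring on that median split them into 6063 higher and 6063 lower, and quantile normalization into 6089 and 6033. The lists named here kept the side of their medians under both scalings, whereas members above -1.79, such as SLC25A37 and JPX, lay above the median feature.

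In H1 cells, the pluripotency mRNAs had higher FPKM in soluble nuclear RNA, and PVT1 and MEG8 were again higher on chromatin, while FTX was not, at -0.19. POU5F1, a core pluripotency factor, had 7.95 FPKM in chromatin and 183 FPKM in soluble RNA, a difference of -4.51. SOX2 stood at -3.54, with 5.06 and 59.9 FPKM, and NANOG at -2.68, with 3.06 and 20.1 FPKM. MEG8 had 16.8 FPKM in chromatin and 0.0935 FPKM in soluble RNA, a difference of 6.45, and PVT1 had 937 and 385 FPKM, a difference of 1.28.

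The annotated H1 feature highest on chromatin was AP001187.9, at 8.70, with 47.5 FPKM in chromatin and 0.0149 FPKM in soluble RNA. FAM73B came next at 6.59, then MEG8, the methyltransferase gene NNMT at 4.97, and the presynaptic protein gene BSN at 3.53. With a pseudocount of 1 FAM73B, at 6.35, lay above AP001187.9, at 5.58. The potassium channel regulator ABCC8 had 2.06 FPKM in chromatin and 0.170 FPKM in soluble RNA. LINC01073, AC005394.1 and RP11-87C12.6 were listed at 0 in soluble RNA, with 10.6, 6.97 and 3.97 FPKM in chromatin. The lowest were ALDH9A1, an aldehyde dehydrogenase, at -7.96, AC025048.1 at -7.51, and ECHS1, a mitochondrial enzyme of fatty acid oxidation, at -7.46. CHPF stood at -7.17, SBK1 at -6.98 and TCEAL8 at -6.96. AC025048.1, ECHS1, SBK1 and TCEAL8 had only 5.81e-05, 0.00024, 0.00063 and 7.47e-05 FPKM in chromatin, values so near 0 that they can be failed estimates. With a pseudocount of 0.01 AC025048.1, ECHS1 and CHPF all lay below ALDH9A1. SOX4 and RP11-534C12.1 were listed at 0 in chromatin, with 20.03 and 19.9 FPKM in soluble RNA.

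All 24 measured pluripotency features of H1 were lower in chromatin, 19 by at least 3-fold, and their median of -2.98 lay at percentile 0.08. Relative to the median of all H1 features, 5 lay above and 19 below. LEFTY2 stood at -4.60 and LIN28B at -4.44, while LINC00678 and DPPA4 were nearer to balance at -0.86 and -1.22. All 24 housekeeping features were lower in chromatin, with a median of -3.74 below all random lists. B2M stood at -4.76, PPIA at -4.55, ACTB at -3.86 and GAPDH at -3.61. Of 82 ribosomal protein features 79 were lower, with a median of -3.05 below all random lists. RPL22L1 stood at -4.22, whereas RPL32 was higher in chromatin at 1.35. Of 59 histone features 56 were lower, with a median of -3.19 below all random lists, and HIST1H4D stood at -4.04. The 19 heme and oxidative stress features were all lower, with a median of -3.09 at percentile 0.01, and SLC7A11, a cystine transporter, stood at -6.33. The 3 mitochondrially encoded features had a median of -3.43 at percentile 8.33, and the largest had 255 FPKM in chromatin and 3109 FPKM in soluble RNA.

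The 8 nuclear lncRNAs of H1 had a median of 0.30, above all random lists, with 4 higher and 4 lower in chromatin. Here too class was not matched, and all H1 lincRNAs had a median of -0.41 against -1.70 for mRNAs. JPX stood at -0.38 and FTX at -0.19. MIAT, in a feature shared with MIATNB, stood at 0.79 and LINC00472, shared with RP3-331H24.5, at 1.09, MALAT1 at -0.65 with 1397 and 2191 FPKM, and NEAT1 at -1.36 with 2.75 and 7.23 FPKM. The 16 germ layer features had a median of -1.61 at percentile 1.67, but at 7.20 with a pseudocount of 1 and 3.74 among features averaging at least 1 FPKM, both inside the central 95%, with KRT18 at -3.45, AFP at -3.37 and COL1A1 at -3.19. The 13 snoRNA host and cytoplasmic lncRNAs had a median of -1.58 at percentile 91.2, with SNHG16 at -2.43, and the 4 small structural RNAs a median of -2.94 at percentile 10.8, with RMRP at -3.51. The 13 erythroid features had a median of -0.79 at percentile 78.0, but -0.32 at percentile 99.7 among features averaging at least 1 FPKM. TFRC, the transferrin receptor, stood at -2.65 and the globin feature of HBG1, HBG2 and HBE1, shared with OR51B5, at -0.06. GATA1 had 0.0123 and 0.0866 FPKM. The 4 myeloid features had a median of -1.35 at percentile 19.4, with ITGA2B at -1.51.

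Over all annotated H1 features, 1484 were higher and 13638 lower in chromatin, with a median of -1.59. Centring gave 7561 and 7561, and quantile normalization 7730 and 7387. Relative to the median of all features, the erythroid, myeloid and snoRNA host lists of H1 lay above it, by 0.81, 0.25 and 0.01, and the snoRNA host list also turned under quantile normalization, to 0.41. Across 7761 features averaging at least 1 FPKM in both lines, the chromatin to soluble difference had a Pearson r of 0.66 and a Spearman rho of 0.68 between K562 and H1. That relation is across features, which are not independent replicates.

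**Figure D1:**
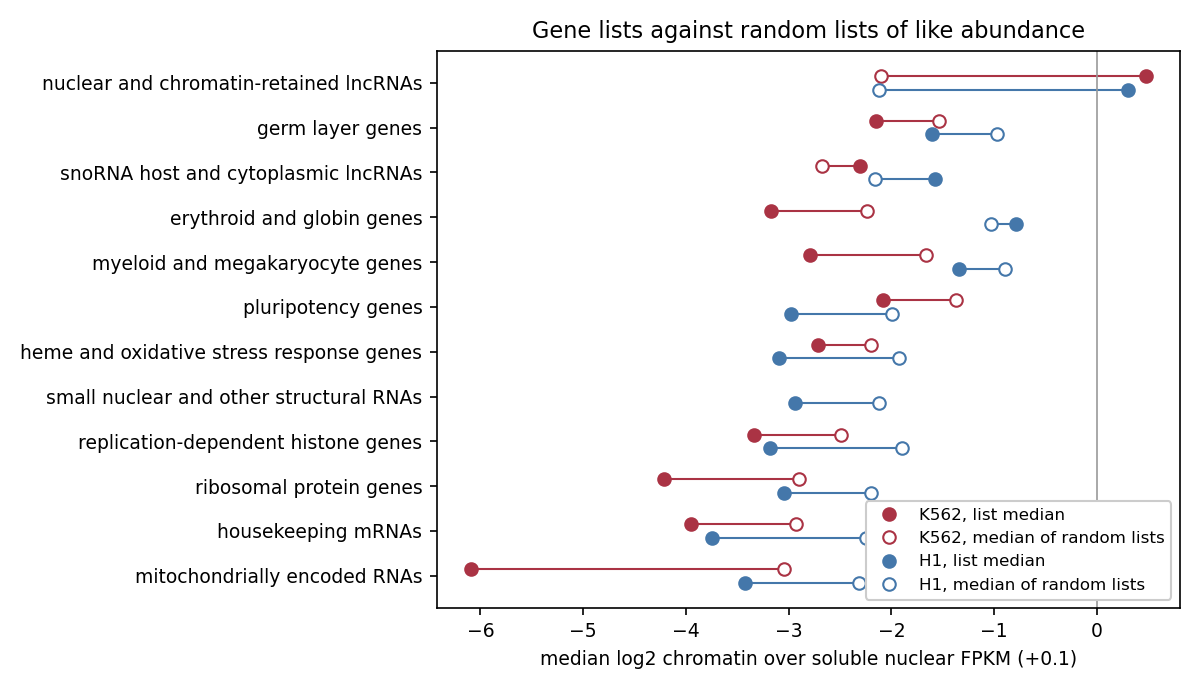
Median log2 ratio of chromatin to soluble nuclear FPKM (with 0.1 added) for each gene list, on the horizontal axis, in K562 (red) and H1 (blue). Filled points are list medians and open points the median of 10000 random lists of like abundance; the nuclear lncRNAs lie at 0.48 and 0.30, and the mitochondrially encoded RNAs at -6.09 and -3.43.

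Coding genes, annotated lincRNAs and cheRNAs were then compared by class. In K562, 424 of 1477 lincRNAs were higher in chromatin, 28.7% (26.4 to 31.1), against 795 of 10650 mRNAs, 7.46% (6.97 to 7.98), an odds ratio of 4.99. In H1, 640 of 1747 lincRNAs were higher, 36.6% (34.4 to 38.9), against 844 of 13375 mRNAs, 6.31% (5.90 to 6.74), an odds ratio of 8.58. The lincRNA medians were -0.81 in K562 and -0.41 in H1, and the mRNA medians -1.92 and -1.70. Centring raised the shares to 77.0% and 81.9% of lincRNAs and 46.2% and 45.8% of mRNAs. Under quantile normalization 47.6% and 48.8% of lincRNAs and 50.6% and 51.6% of mRNAs were higher. These class counts do not add up to the quantile counts of all annotated features, so each class appears to have been normalized on its own. Such scaling evens out the higher and lower counts within a class, so these shares cannot show whether the classes differ.

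The cheRNAs had a median of 1.99 in K562 and 1.38 in H1, and each was higher in chromatin, the property the class is named for. With 0.1 FPKM added to both fractions, 2588 of 3293 in K562 and 320 of 1136 in H1 were at least 3-fold higher. By the FPKM values alone, and among cheRNAs without the location and values of an annotated entry, 2887 of 3264 in K562 and 549 of 1130 in H1 were. Their median levels were 1.15 FPKM in K562 chromatin and 1.47 FPKM in H1 chromatin.

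**Figure D2:**
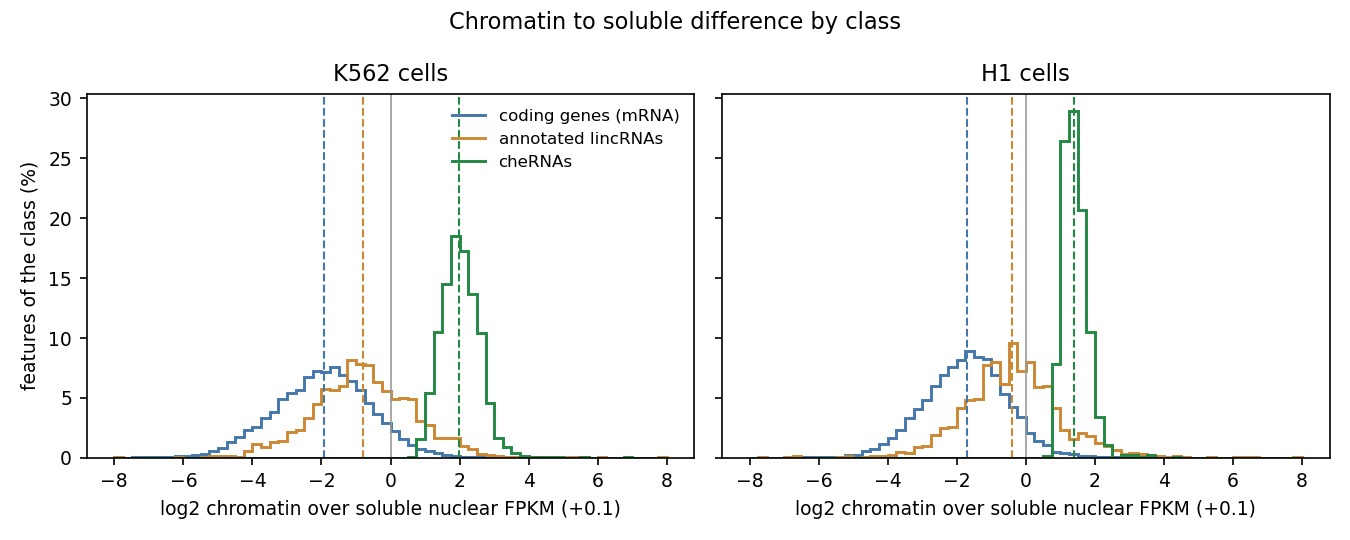
Share of features (percent, vertical axis) by log2 ratio of chromatin to soluble nuclear FPKM (with 0.1 added, horizontal axis) for mRNAs, annotated lincRNAs and cheRNAs in K562 and H1. Dashed lines are class medians, which for cheRNAs lie at 1.99 and 1.38; values beyond the axis are counted in the outermost bins.

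Of the 6 K562 cheRNAs highest in chromatin, 4 had the location and values of an annotated gene. XLOC_036465 on chromosome 3, from 186781779 to 186807122, had 700385 FPKM and the values of EIF4A2, a translation initiation factor. XLOC_054859 had the values of RPL10, XLOC_022724 those of TMEM107 and XLOC_033977 those of RANBP1. XLOC_032770 on chromosome 20, from 38418269 to 38435353, had 288608 FPKM in chromatin and 24451 FPKM in soluble RNA. XLOC_046878 on chromosome 7, from 65647009 to 65770810, had 82462 and 4407 FPKM. In H1 the highest was XLOC_036394 on chromosome 3, from 180983708 to 181836880, the location that also carries SOX2, with 67.3 FPKM in chromatin and 3.21 FPKM in soluble RNA. XLOC_034213 on chromosome 22, over PITPNB, had 53.8 and 4.36 FPKM, and XLOC_024325 had the values of CTIF. CLOC_268826 and CLOC_268824 lay side by side on chromosome 9, with 24.3 and 16.4 FPKM in chromatin, and CLOC_279724 lay on chromosome X with 16.8 FPKM.

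No noncoding entry of either table lay in the beta-globin region of chromosome 11, from 5200464 to 5294945. The nearest K562 cheRNA, CLOC_028571, from 5135215 to 5137439, had 0.922 FPKM in chromatin and 0.347 FPKM in soluble RNA and was chosen after its value was seen.

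To see how far the cheRNAs are shared between cell types, the 3264 K562 and 1130 H1 cheRNAs without the location and values of an annotated entry were overlapped. A cheRNA that shares only the location of an annotated entry, such as XLOC_036394 with SOX2, was kept. Of the K562 cheRNAs 84 overlapped an H1 cheRNA by at least 1 base, 2.57% (2.06 to 3.18), and of the H1 cheRNAs 84 overlapped a K562 one, 7.43% (5.97 to 9.12). When the K562 cheRNAs were shifted along their chromosomes 1000 times, the median overlap was 9 and the highest 66. Of the 660 annotated lincRNAs that could be given a position and were higher in soluble RNA of K562, 297 overlapped such a lincRNA of H1, 45.0% (41.2 to 48.9), and the odds ratio of cheRNAs to lincRNAs was 0.0323. The lincRNAs come from 1 annotation used in both tables, which favours their overlap. The cheRNAs were short, with median spans of 2799 bp in K562 and 3304 bp in H1, and the comparison was not matched on length. They also lay in runs, 902 groups in K562 and 440 in H1 at gaps of up to 10 kb. The intervals count each cheRNA on its own and may therefore be too narrow. No K562 cheRNA lay inside the merged loci of chromosomes 1 and 11, where 73 H1 cheRNAs lay.

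The coding genes nearest to cheRNAs were more abundant on chromatin in K562 than those nearest to annotated lincRNAs. Of the K562 cheRNAs on chromosomes with coding genes, 38.4% lay within 100 kb of one, and the median gap was 194128 bp. In H1 58.8% did, and the median gap was 60603 bp. The comparison within 100 kb leaves out the rest. Among 1098 K562 genes whose nearest noncoding transcript within 100 kb was a cheRNA, the median was 1.87 FPKM, against 1.26 FPKM for 1922 genes nearest to a lincRNA and 0.411 FPKM for 12604 genes with neither. The log2 difference was 0.54 (0.05 to 0.87 by resampling genes), and 845 of 100000 random relabelings gave one as large. In H1 the medians were 1.51 FPKM for 645 genes, 1.15 FPKM for 2424 and 0.695 FPKM for 14234, a difference of 0.37 (-0.01 to 0.64), which 2451 of 100000 relabelings reached. Relabeling treats genes as independent, but cheRNAs lay in runs and neighbouring genes can share a label, so these shares may be too small. Labels were not shifted along the genome for this comparison. Within 10 kb the differences were 1.15 in K562 and 0.93 in H1. Within 1 Mb the K562 difference turned to -0.35 (-0.60 to -0.13), which 195 of 100000 relabelings reached, and that of H1 was 0.03, which 75912 reached. With cheRNAs at least 3-fold higher by the FPKM values alone, 6085 relabelings reached the K562 difference of 0.38 (-0.03 to 0.82) and 7785 the H1 difference of 0.36, so neither passed a share of 0.05. Without noncoding transcripts that overlap a coding gene, 7852 relabelings reached the K562 difference of 0.39 and 11030 the H1 difference of 0.28. The differences were not particular to chromatin: in soluble RNA they were 0.53 in K562 and 0.39 in H1, which 714 and 1079 relabelings reached. All cheRNAs had at least 0.497 FPKM in K562 chromatin or 0.678 FPKM in H1 chromatin, whereas lincRNAs needed a mean of 0.1 FPKM. The part of this unlike abundance in the differences was not tested.

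Coding genes near a cheRNA of 1 line lay higher in that line. Among 15589 shared genes, the 1054 with a cheRNA within 100 kb in K562 alone had a median K562 to H1 log2 difference of 0.30 in chromatin RNA, and the 489 with one in H1 alone had -0.35, both relative to the median over shared genes of separately normalized tables. Their difference of 0.65 (0.44 to 0.88) was reached by 0 of 100000 relabelings of genes and, with labels shifted along the genome to keep neighbours together, by 0 of 10000 shifts. Within 10 kb it was 1.29 (0.86 to 1.77), and within 1 Mb 0.11 (0.05 to 0.18). Among the 10677 coding genes at 1 FPKM or more in at least 1 line, a limit chosen after the data were seen, it was 1.13 (0.85 to 1.37). Of the K562 group 58.2% of genes lay above the shared median, and of the H1 group 33.5%. That median was 0 in chromatin RNA, so setting levels relative to it changed no value there. Genes with no cheRNA within 100 kb in either line also had a median of exactly 0, so many genes may be tied there. The share of all shared genes above that median is not given, so these shares lack a baseline.

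Genes at the ends of both groups were chosen after their values were seen. RHAG, the erythroid Rh-associated glycoprotein, lay 0.517 kb from CLOC_167187 on chromosome 6 and had 33.3 FPKM in K562 chromatin and 0.218 FPKM in H1 chromatin, a difference of 6.71. The blood transcription factor gene LYL1 lay 52.2 kb from CLOC_085804 and stood at 5.62, and the growth factor gene IGF1 lay 0.61 kb from CLOC_041292 and stood at 6.02. CPED1 had the largest difference, 8.37, at 46.3 kb from CLOC_182906. Between CPED1 and RHAG lay HIST1H2AG at 7.36, RPL39 at 7.03, HIST1H1D at 6.93 and PYDC2. PYDC2 was listed at 0 in H1 chromatin, with 10.5 FPKM in K562 chromatin. The ribosomal protein gene RPL39 had 53.1 FPKM in K562 chromatin and 0.307 FPKM in H1 chromatin. Such ends may therefore also hold failed estimates and are not only genes of 1 cell type. In the H1 group, SOX2 was listed at 0 in K562 chromatin with 5.06 FPKM in H1 chromatin. It lay inside the location of XLOC_036394, which is also the location listed for SOX2. That overlap therefore does not show nearness to a separate cheRNA. APP, the amyloid precursor gene, lay 9.21 kb from CLOC_155216 and stood at -7.08. PAWR, a regulator of apoptosis, lay 44.8 kb from CLOC_062401 and stood at -8.60. PHF21B and the neuronal RNA-binding protein gene ELAVL2 were listed at 0 in K562 chromatin, with 31.7 and 8.97 FPKM in H1 chromatin. DOCK1, CTGF, SPP1 and GPC4 lay farther out than SOX2, with SPP1 at -6.09 and GPC4 at -5.84. DOCK1 and CTGF, like SOX2, were listed at 0 in K562 chromatin, with 8.64 and 7.25 FPKM in H1 chromatin. The places of genes listed at 0 in that order depend on the 0.1 FPKM added.

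**Figure D3:**
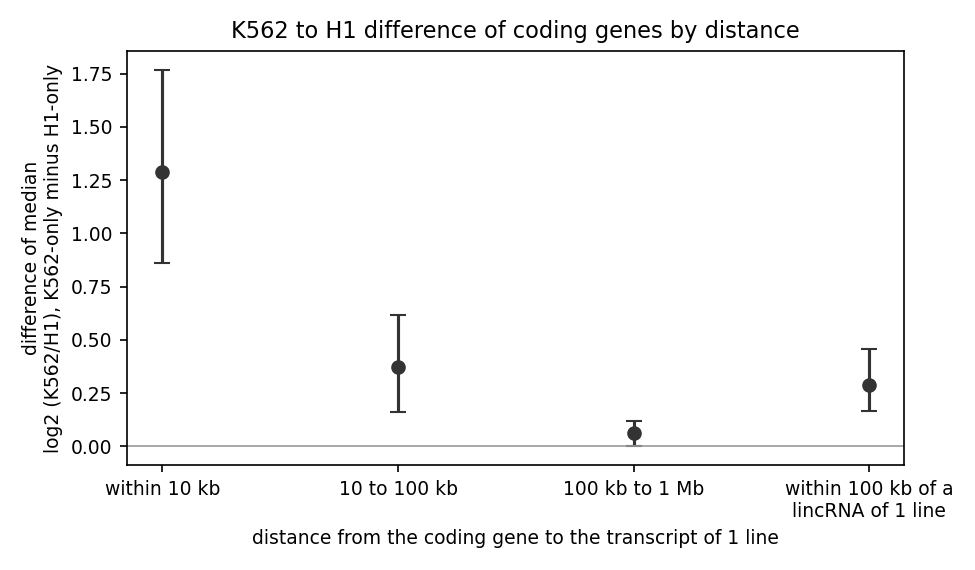
Difference in median log2 ratio of K562 to H1 chromatin FPKM (vertical axis) between coding genes near a noncoding transcript of K562 alone and of H1 alone, by distance. Points are differences and bars 95% intervals from resampling genes; the first 3 points are for cheRNAs, at 1.29, 0.38 and 0.06, and the last for annotated lincRNAs measured in 1 line, at 0.29.

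The fixed lists gave the levels of marker genes in both lines, relative to the median over 13446 shared features of separately normalized tables. In soluble RNA 21 of 22 erythroid features lay higher in K562, with a median difference of 7.24, and 13 of 14 pluripotency features lower, with a median of -8.69. These lists lay above all and below all 10000 random lists of like abundance. The 7 myeloid features had a median of 2.72 at percentile 99.9, with 6 higher in K562, and 9 of 11 germ layer features lay lower in K562, with a median of -1.95 at percentile 1.64. In chromatin RNA the erythroid median was 4.79 and the pluripotency median -5.69, while the myeloid median of 1.04 and the germ layer median of -0.75 lay at percentiles 97.3 and 8.10, inside the central 95%. The histone lists lay at 1.07 in chromatin and 1.20 in soluble RNA, at percentiles 99.95 and 99.0. The 3 mitochondrially encoded features all lay lower in K562 chromatin, with a median of -1.87 at percentile 1.51, and at 0.21 in soluble RNA at percentile 25.3. Of 68 ribosomal protein features 64 lay higher in K562 soluble RNA, with a median of 1.26 at percentile 99.7, and 52 higher in K562 chromatin RNA, with a median of 0.39 at percentile 45.2.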

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

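Alternatives that centre on the median, leave out features listed at 0 or above 2000 FPKM, restrict proximity to other genes or lincRNAs, add a pseudocount of 1 to proximity or shift labels along the genome were chosen after the data were seen. No paired analysis was possible because each fraction holds 1 pooled value, and the replicate block, leaving out replicates, a stricter q, other count normalizations and every hemin comparison were not run. Depth is unknown and sets no stated limit. Of the alternatives for main results 118 kept the result, 27 moved it, 9 left it weaker, 3 stronger and 1 reversed; the 118 include counts of higher and lower features under other pseudocounts, which cannot change them. The cause of each change was not tested unless the setting itself removes features. In K562, features higher in chromatin numbered 2898 without a filter, 516 at a mean of 1 FPKM, 171 at 3-fold, 352 at 2-fold, 6089 after quantile normalization and 6063 after centring, and features lower in chromatin 6782 at 3-fold, 6033 after quantile normalization and 6063 after centring. In H1 the higher ones numbered 3340, 378, 209, 382, 7730 and 7561 under the same settings, and the lower ones 7599, 7387 and 7561. The share of mRNAs higher in chromatin was 0.779% at 3-fold and 4.92% at 1 FPKM in K562 and 0.493% and 2.85% in H1, and that of lincRNAs 5.96% and 20.2% in K562 and 8.19% and 21.2% in H1. With a pseudocount of 1 the K562 erythroid median was -2.55 (percentile 3.84), the K562 pluripotency median -1.47 (2.16) and the H1 germ layer median -0.46 (7.20). At 1 FPKM the K562 histone median was -3.42 (3.86), the H1 erythroid median -0.32 (99.7) and the H1 germ layer median -3.28 (3.74). Without features listed at 0 the K562 myeloid median was -2.79 (2.17). The overlap of K562 with H1 cheRNAs was 1.04% at 3-fold by the FPKM values alone. The abundance difference near cheRNAs within 1 Mb was -0.35 in K562, reversed, and 0.0262 in H1; without transcripts that overlap a coding gene it was 0.39 and 0.28, and with cheRNAs at least 3-fold enriched 0.38 and 0.36, no longer past a share of 0.05 of relabelings. The K562 to H1 difference of genes near cheRNAs stayed above 0 and past that share under all 7 of its alternatives, of which shifted labels leave the value itself unchanged. Single genes were recomputed with a pseudocount of 1 or 0.01, which cannot change a sign: 29 values moved by less than 0.1 and 31 by more. Some extremes moved far, PAGE1 from -8.53 to -5.24 and -11.84 and AP001187.9 from 8.70 to 5.58 and 10.90. The pseudocount therefore largely sets such values and their order.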

Other observations

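Other groups of coding genes, chosen after the values were seen, were also placed among random lists. In K562 the 265 ZNF zinc finger genes had a median chromatin to soluble difference of -1.42, above all 10000 random lists, and in H1 301 of them had -1.48, likewise above all. The 51 respiratory chain genes had -4.08 in K562 and 53 had -3.29 in H1, and the mitochondrial ribosomal protein genes had -3.43 and -2.95, all 4 values below all random lists. The 27 proteasome subunit genes of K562 had -2.81 at percentile 33.2, and the 30 of H1 -2.89 at percentile 0.63. In H1 the 6 protocadherin genes had -2.19 at percentile 24.98.

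The cheRNAs lay in runs. At gaps of up to 10 kb the 3264 of K562 formed 902 groups and the 1130 of H1 440. The fullest K562 run held 54 cheRNAs on chromosome 2, from 78130935 to 78387611, with LRRTM4 as the nearest coding gene, 608559 bp away. Another held 49 on chromosome 4, from 126369881 to 126768744, with a median of 10.9 FPKM in chromatin and 2.34 FPKM in soluble RNA. The fullest H1 run held 28 on chromosome 2, from 117352822 to 117622833, with DDX18 as the nearest coding gene, 191858 bp away. Another held 26 on chromosome X, from 23467918 to 23657140, 10.4 kb from PRDX4.

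Of the tests that follow, those on lincRNAs of 1 line and on gene length were set before their results were seen, and the others after. Coding genes near K562-only cheRNAs lay higher in K562 than genes near H1-only ones. Gene dosage or an active domain of 1 Mb as the whole cause would give as large a difference farther away, but at 100 kb to 1 Mb it was 0.0611 (0 to 0.12), under the lower bound of 0.44 within 100 kb. Among genes at 1 FPKM or more in at least 1 line it was 0.29 (0.15 to 0.43), under the lower bound of 0.85 within 100 kb but above 0, so a smaller part stays open. Reads running on for up to 10 kb from the compared gene itself would leave none beyond, but at 10 to 100 kb it was 0.38 (0.16 to 0.62). That value cannot set aside run-on over longer distances or from another gene beside the cheRNA. Any line-specific noncoding transcription nearby stays a candidate explanation, since annotated lincRNAs measured in 1 line gave 0.29 (0.17 to 0.46), and a regulatory effect of the cheRNAs themselves was not tested.

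Many K562 genes were listed at 0 in both fractions inside 7 merged loci on chromosomes 1 and 11, where 93.3% of 3142 annotated entries were at 0. H1 had 1 merged locus, on chromosome 1 from 601435 to 50203786, with all 430 annotated entries at 0. Silent genes in K562 are argued against by housekeeping and ribosomal protein genes such as ENO1, RPL11 and RPS3, since 100% of those in the K562 merged loci were at 0. Of the coding genes at 0 in the K562 merged loci and placed outside that of H1, 58.3% (55.8 to 60.7) reached 1 FPKM in H1 soluble RNA, against 9.47% (8.44 to 10.6) of K562 genes at 0 elsewhere, consistent with failed estimates. The H1 value is from another line, so it cannot speak for single genes.

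In K562 33 features exceeded 2000 FPKM in chromatin and held 96.8% of the summed FPKM. Of these 97.0% (84.2 to 99.9) held a small structured RNA, against 21 of 637 features of like span, 3.30%, so reads of small RNAs inside them may set their values. Whether the K562 chromatin libraries held more small RNA in general cannot be told apart: features with a small RNA differed from others by -0.0201 (-0.13 to 0.10) in the K562 to H1 level, an interval that reaches the bound of 0.1 set for no difference. The 16 such features above 2000 FPKM that both tables hold, among them RMRP, RPS2, EIF4G2 and SNHG8, lay higher in K562 chromatin by a median of 4.66, but they were chosen for high K562 values. In soluble RNA these 16 also all lay higher in K562, by a median of 2.76. The doubt is not particular to K562. In H1 15 features exceeded 2000 FPKM in chromatin, among them SNHG1 and SNHG8. All 15 held a small structured RNA, 100% (78.2 to 100), against 8 of 295 features of like span, 2.71%.

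The longest quintile of coding genes had a chromatin to soluble difference 1.05 above that of the shortest quintile in K562 and 0.95 above it in H1. On chromosome 1 K562 had 11 cheRNAs and H1 46, with merged loci there in both lines, and 73 H1 cheRNAs lay inside the K562 merged loci.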
